A study of Drosophila melanogaster with 2 samples.

How the data were processed

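ChIP-seq for GFP-tagged Corto was done on whole Drosophila melanogaster embryos of mixed sex, aged 0 to 24 h. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp, and the 2 libraries were separate biological replicates of 1 group.

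The authors deposited peak lists in the narrowPeak format on 2 genome builds, dm6 and dm3. Per the text notes deposited with the lists, each replicate's list of peaks and background, and a pooled list of both replicates, was made from alignments together with a control. Each such list held 30000 entries. The optimal peak set was then derived by the authors from the replicate and pooled lists with the irreproducible discovery rate, a measure of how reproducibly a peak is ranked in both replicates. The aligner, the peak caller, the discovery rate threshold and read filters are not given in the sources used here, and the control reads were not analysed here. Peaks were thus called per replicate and on pooled reads, and the replicate lists were compared with each other.

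The deposited peak signal is the signal column of the narrowPeak format. Whether it is a fold over the control or another score of the peak caller is not given in the sources used here, so it was used only to describe and rank peaks within a list, and log2 differences of it are in its own unknown scale. The deposited −log10 q values of the dm6 optimal set ran from 1.79 to 3.36, with 1158 peaks tied at the maximum, and were not used for ranking. The summit was taken from the deposited offset from the peak start. No read counts were used, so depth is unknown and no interval for a single peak's signal is given. Intervals on shares of peaks or genes are 95% Wilson intervals and cover counting error only. A count of 0 was given with the share that 3 counts would make.

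Coordinates are 1-based on dm6. Genes were taken from Ensembl release 115 for the matching assembly (BDGP6.54) and sequence from the NCBI genome of the same assembly. The peaks ended inside the arms, and 99.5% of annotated coding sequences started with ATG in this sequence. The background held 13945 protein-coding genes with 19607 TSSs on arms X, 2L, 2R, 3L, 3R and 4. The dm3 lists were used for counts, replicate overlap, rank correlation and chromosome densities only, with no conversion of coordinates.

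A promoter summit lay within 500 bp of a protein-coding TSS, and a gene with such a summit at any of its TSSs was called bound. Locations were assigned in the order promoter, 5′ UTR, coding sequence, 3′ UTR, intron or non-coding exon, intergenic. Shares were set against 1000 circular shifts of the summits within each arm, and the replicate overlap against 100 shifts. Gene lists, divergent promoters and gene classes were tested with Fisher's exact test, motifs with the exact McNemar test in windows of 100 bp on either side of the summit against a window 1000 bp away, and densities and signals with permutation tests of 100000 resamples. All tests were two-sided, with a threshold of 0.05 after Benjamini-Hochberg adjustment within each family.

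The groups, the 16 gene lists, the 17 motifs, the tests and most alternatives were fixed before the data were examined. Older gene names in the lists were matched to current symbols after that. The lists covered Hox genes, developmental regulators, Polycomb and Trithorax group genes, cytoplasmic and mitochondrial ribosomal proteins, ribosome biogenesis, heat shock, ecdysone response, cell cycle, signalling, neural and muscle genes, histones, odorant and gustatory receptors and cuticle proteins. Named genes were corto, the nearest genes of the 10 strongest peaks after merging within 1000 bp, the 8 Hox genes, the 3 bound members with the strongest promoter summit of each list called higher, and 1 such member of each other list with any. One gene that this rule names is not reported here.

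The alternatives were a stronger part of the optimal set, each replicate alone, merged summits, promoter windows of 250 and 1000 bp, the dm3 lists, bins of 500 kb, other summit distances and numbers of top peaks, other motif windows and controls, other list backgrounds, and list genes with TSSs within 5 kb of each other counted once. Added after seeing the data were flanks matched on GC content, shifts within the span of the pooled list, correlation over the pooled list, lists without corto, each summit given only to the gene of its nearest TSS, linked list genes as 1 unit that is bound if any of them is, matching on more classes of TSS number, lists without ph-d, and the upstream share against shifts and at TSSs with none of the opposite strand within 1000 bp. The matching otherwise took genes with 4 or more TSSs as 1 class.

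The calculations were tested on simulated data. In 200 simulations, 40% of the genes of 1 list were bound. Such lists were called in 86.9% of cases with 18 or more genes and in 15.4% with 8 genes. Of lists with nothing added, 0.333% were called. Genes were bound independently and at a common rate there, so linked genes, shared promoters and unequal numbers of TSSs are not covered. A promoter share made at 28.5% of 2644 summits was found at 28.3%, a motif written at 5% of 2600 summits gave a difference of 4.73 points, and 50% of shared summits were found as 51.2%. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.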

Results

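Corto is a Drosophila chromodomain protein encoded by corto, a gene classed among the Enhancers of Trithorax and Polycomb, whose mutations affect both gene groups that maintain homeotic gene expression and silencing. The sites it occupied in embryos were mapped by ChIP-seq, in which DNA bound to a protein is precipitated with an antibody and sequenced. The fly line carried a Corto fusion with green fluorescent protein (GFP) at its C terminus, and an antibody against GFP was used. Whole embryos of both sexes aged 0 to 24 h gave 2 biological replicates of 1 group, so no comparison between conditions exists. The deposited values are peak positions and peak signals without read counts, and the sequencing depth of the 2 replicates is therefore unknown. All signals below are the deposited peak values, whose scale is not given in the sources used here, used to describe and rank peaks within a list, and all coordinates are on dm6.

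The optimal peak set, which the authors derived from both replicates with the irreproducible discovery rate (IDR), held 2644 peaks on the 6 chromosome arms X, 2L, 2R, 3L, 3R and 4. Signals ran from 81.2 to 1209 with a median of 113. Merging summits within 500 bp left 2550 regions, and the dm3 version of the set held 2604 peaks. These 2644 peaks were the strongest 8.81% of the 30000 entries of the pooled list, with no exception.

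Both replicates placed their strong peaks at the same sites far more often than chance. Of the 2644 strongest peaks of replicate 1, 57.5% (95% Wilson interval 55.6 to 59.3) had a top summit of replicate 2 within 200 bp. Circular shifts of the replicate 2 summits gave 0.806% on average and 1.48% at most (permutation by shifts, p = 0.0198, two-sided, the smallest that 100 shifts can give). The share was 63.7% for the top 1000 peaks. A summit lay within 200 bp in both replicate lists for 2551 optimal peaks (96.5%), and the summits of the replicates were a median of 36 bp apart. Spearman's rho of the replicate signals across these peaks was 0.44. Peaks are not independent replicates, and the set was selected on pooled signal, which restricts this correlation; in the weaker part of the set, rho was −0.55. Both replicates ranked 1425 optimal peaks (53.9%) among their own strongest 2644, and 99 of the 100 strongest optimal peaks were among them. The optimal set was derived from these same replicates, so these matches and the 96.5% above are in part built in.

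The strongest peak, with a signal of 1209, lay in an intron or non-coding exon of CG11050 at 2L 6612443 to 6612875, with the summit 990 bp from the nearest transcription start site (TSS). It ranked 1 in both replicates, with signals of 593 and 668. The next lay within ush at 2L 481043 (signal 846), where the nearest TSS was that of cbt, a gene for a zinc finger transcription factor, at 1355 bp. An intergenic summit at 2R 13035323 (766) was 11933 bp from the nearest TSS, that of CG13323. Summits followed within Lk6, a kinase gene (3R 11760902 to 11761169, signal 724), and 5733 bp from eEF1gamma, which encodes a translation elongation factor subunit (3R 29214439, signal 700). Promoter summits with signals from 652 to 679 lay 164 bp from Gapdh2, a glycolytic enzyme gene, 76 bp from PNPase, 86 bp from CG14100 and 21 bp from Ugalt, a gene for a UDP-galactose transporter. The last of the 10 strongest sites was inside osa, which encodes a subunit of the Brahma chromatin remodelling complex, at 3R 17704417 (626).

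Summits lay mainly at promoters and in introns, and almost never in coding sequence. Of the 2644 summits, 1156 (43.7%, 95% Wilson interval 41.8 to 45.6) were within 500 bp of a protein-coding TSS, against 11.5% of circularly shifted summits, a 3.80-fold excess. Coding sequence held 3 summits (0.113%) against 13.9% after shifts, in CG43389 (signal 415), CG12054 (102) and CG3919 (83.5), genes named here because the count was small. Introns or non-coding exons held 1010 summits (38.2%), close to the shifted 39.1% (permutation by shifts, adjusted p = 0.537). Intergenic sequence held 417 (15.8% against 30.2%), 3′ UTRs 24 (0.908% against 4.47%) and 5′ UTRs 34 (1.29% against 0.786%). After Benjamini-Hochberg adjustment over the 6 places, the permutation p of the promoter, coding, intergenic and 3′ UTR shares was 0.003, the smallest that 1000 shifts allowed here, and that of 5′ UTRs was 0.0192. The weaker entries of the pooled list were less often at promoters (21.6%) and more often in coding sequence (2.93%).

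**Figure D1:**
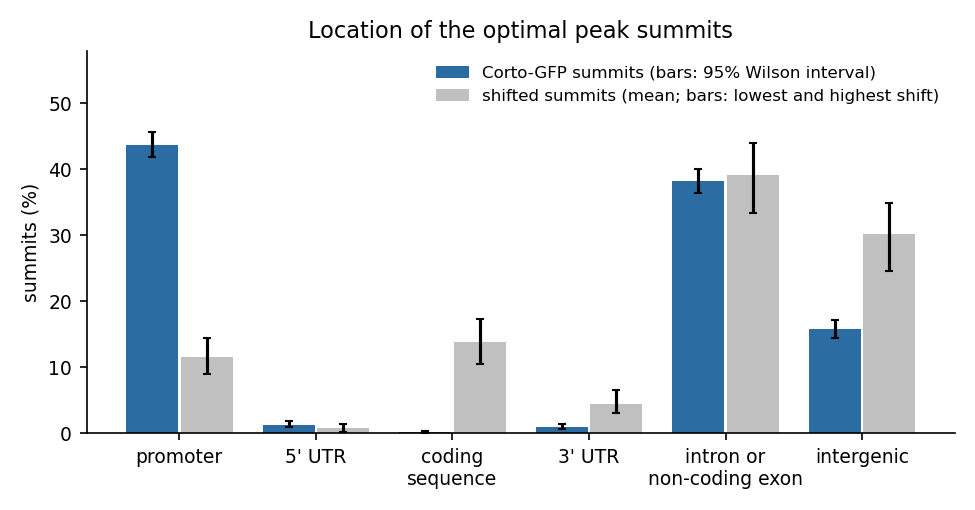
Share of the 2644 summits in each kind of sequence in percent (blue, with 95% Wilson intervals) beside the mean of 1000 circular shifts (grey, with the lowest and highest shift). Promoters held 43.7% against 11.5% and coding sequence 0.113% against 13.9%.

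Promoter summits sat just upstream of the TSS. Of the 1156, 943 were upstream of the nearest TSS, 212 downstream and 1 on it, so that 81.6% (95% Wilson interval 79.3 to 83.8) of the summits off the TSS were upstream (exact binomial test against equal sides, two-sided, p = 2.18e-110). A summit between 2 divergent TSSs is upstream of both, so 2 more values were taken after seeing the data. Circularly shifted summits near a TSS were upstream in 45.1% of cases on average and 54.7% at most (permutation p = 0.002, the smallest that 1000 shifts allow). At TSSs with none of the opposite strand within 1000 bp, 628 of 750 summits (83.7%) were upstream, against a shifted mean of 49.98%. The median offset was −121 bp, with quartiles of −212 and −38.8 bp.

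**Figure D2:**
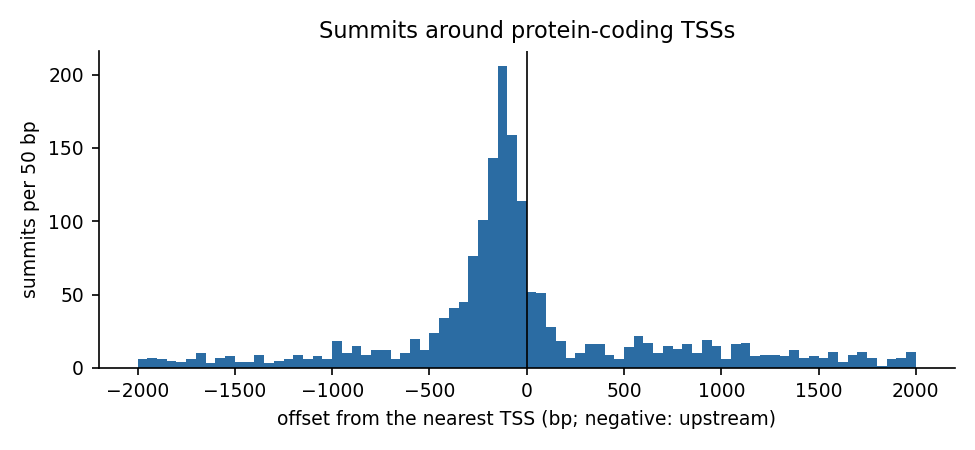
Number of optimal summits per 50 bp by offset from the nearest protein-coding TSS in bp, negative upstream. The summits pile up just upstream of the TSS, with a median of −121 bp among those within 500 bp.

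Going down the pooled list in steps of 3000 peaks, the promoter share fell from 43.5% to 13.0%, while the coding share was 0.1% in the first step and 5.43% in the last. These steps count as coding also the summits that lie in a 5′ UTR of another transcript, which the shares above count as 5′ UTR. Within the optimal set, promoter summits had a median signal of 114.9 and the 917 summits more than 2 kb from any TSS one of 110. The difference of 0.06 on the log2 scale was small (permutation test, two-sided, p = 0.0373) and did not pass in the strongest peaks of replicate 2 alone (p = 0.139) or of replicate 1 alone (p = 0.267). Of the 100 strongest summits, 54% were at promoters.

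**Figure D3:**
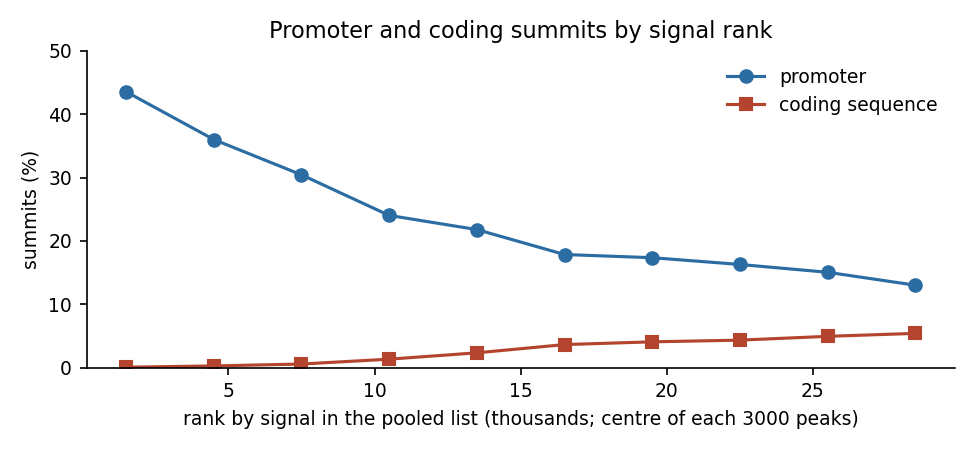
Share of summits at promoters (blue circles) and in coding sequence (red squares) in percent, for consecutive groups of 3000 peaks of the pooled list ordered by signal. The promoter share goes from 43.5% to 13.0% and the coding share from 0.1% to 5.43%.

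The X chromosome and the autosomes did not differ detectably in summit density. The X had 17.9 ± 9.60 summits per Mb (mean ± SD over 23 bins of 1 Mb) and arms 2L, 2R, 3L and 3R had 20.6 ± 13.0 (108 bins). The difference of −2.67 per Mb was within the spread of the bins (permutation test, two-sided, p = 0.352). It was −4.43 per Mb on the dm3 lists (permutation p = 0.0787) and −0.682 in the stronger part of the peak set (0.663). Chromosome 4 carried 7 summits, or 5.19 per Mb, and was not part of the test.

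Promoter summits assigned 1381 of the 13945 protein-coding genes on the arms as bound (9.90%), where shifted summits gave a mean of 325 and at most 399. Bound genes often shared their promoter region with a gene on the opposite strand. A divergent partner TSS within 500 bp upstream was present for 671 bound genes (48.6%) and 3144 of 12564 unbound genes (25.02%; Fisher's exact test, two-sided, p = 2.54e-70). A summit between 2 such TSSs counts for both genes. When each summit was given only to the gene of its nearest TSS, an alternative chosen after seeing the data, 1037 genes were bound and the shares were 35.4% and 26.7% (Fisher's exact test, p = 4.07e-09).

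Corto-GFP was found more often than in other genes at promoters of genes of the ecdysone response, heat shock, the Polycomb and Trithorax groups and cytoplasmic ribosomal proteins. These were 5 of the 16 gene lists fixed beforehand, each set against all other protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Each of these calls was lost under some alternatives. Promoters of odorant and gustatory receptors, cuticle proteins and replication-dependent histones carried no summit. The other 8 lists did not pass the threshold.

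Of 19 ecdysone response genes, which answer the moulting hormone, 8 were bound (42.1%, 95% Wilson interval 23.1 to 63.7, against 9.86% of other genes; adjusted exact p = 0.00134). They included the nuclear receptor genes Eip75B, with a summit 11 bp from a TSS at 3L 17999810 (signal 279, 136 and 154 in replicates 1 and 2), EcR, the ecdysone receptor gene (2R 6132131, signal 181), and Hr96 (3R 25025082, signal 170). Eip75B, a gene of 114 kb, had 14 optimal summits within its span and 5 kb on either side, and EcR had 8. Single shifts of the summits gave up to 19 at Eip75B.

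Of 18 heat shock genes 7 were bound (38.9%, interval 20.3 to 61.4; adjusted exact p = 0.00292). Counting neighbours within 5 kb once, the call depended on how a cluster was scored. With its first gene kept, 3 of 11 were bound (adjusted exact p = 0.174), and with linked genes as 1 unit, bound if any gene was, 4 of 9 were (0.0213), the latter chosen after seeing the data. Hsp27, a small heat shock protein gene, had one of the strongest promoter summits of the set (3L 9383908, 155 bp from the TSS, signal 622, rank 12, with 321 and 298 in the replicates). Hsp83, the Drosophila Hsp90 gene (3L 3193129), had a signal of 225, and Hsp26 (3L 9377657), in the same cluster as Hsp27, had 169.

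Of 24 Polycomb group genes, encoding or assisting silencing complexes, 8 were bound (33.3%, interval 17.97 to 53.3; adjusted exact p = 0.00313). Of these 8, ph-d, Sfmbt and lolal had no summit of replicate 2 within 200 bp, and lolal ranked 12988 in replicate 1. In the whole optimal set, 96.5% of peaks had such a summit in both replicates. The strongest summit was at ph-p, a gene of Polycomb repressive complex 1, at X 2137319 (signal 616, 346 and 289 in the replicates). Its tandem copy ph-d was bound as well, with a signal of 107, and near-identical copies can share reads. Without ph-d, chosen after seeing the data, the list still passed (adjusted exact p = 0.0108). Summits at jing (2R 6501895, signal 148) and E(z), the H3K27 methyltransferase gene (3L 10638019, signal 122), followed. Of 29 Trithorax group genes 9 were bound (31.03%, interval 17.3 to 49.2; adjusted exact p = 0.00313), corto itself, the tagged gene, among them. Without corto, chosen after seeing the data, the gap to other genes was 18.7 points (adjusted exact p = 0.0092). The bound genes included brm, the ATPase gene of the Brahma remodeller (3L 15982979, signal 247), Trl, which encodes GAGA factor (3L 14757372, signal 178), and tna (3L 10857653, signal 132).

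Of 86 cytoplasmic ribosomal protein genes 19 were bound (22.1%, interval 14.6 to 31.9; adjusted exact p = 0.00292). RpL34b (3R 9401405, signal 207) and RpL7 (2L 10201008, signal 194) were among those with the strongest summits, 179 and 4 bp from a TSS. The mitochondrial ribosomal protein genes did not pass (10 of 73, 13.7%; adjusted exact p = 0.429), with the strongest summit at mRpL41 (2R 15217742, signal 309), but did so without replicate 2 (adjusted exact p = 0.0120).

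No summit was found at the promoters of 119 odorant and gustatory receptor genes (adjusted exact p = 1.18e-04; a count of 0 allows up to 2.52%), 70 cuticle protein genes (adjusted exact p = 0.00292; up to 4.29%) and 111 histone genes (adjusted exact p = 1.35e-04; up to 2.70%). The histone genes lie in tandem repeats, and none had a summit even in the pooled list, where 9 receptor and 15 cuticle protein genes had one. As the read filters are not given, a lack of binding cannot be judged at these repeats. With neighbours within 5 kb counted once they were 22, and the call ended (adjusted exact p = 0.285); linked into units they were 2 (1).

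**Figure D4:**
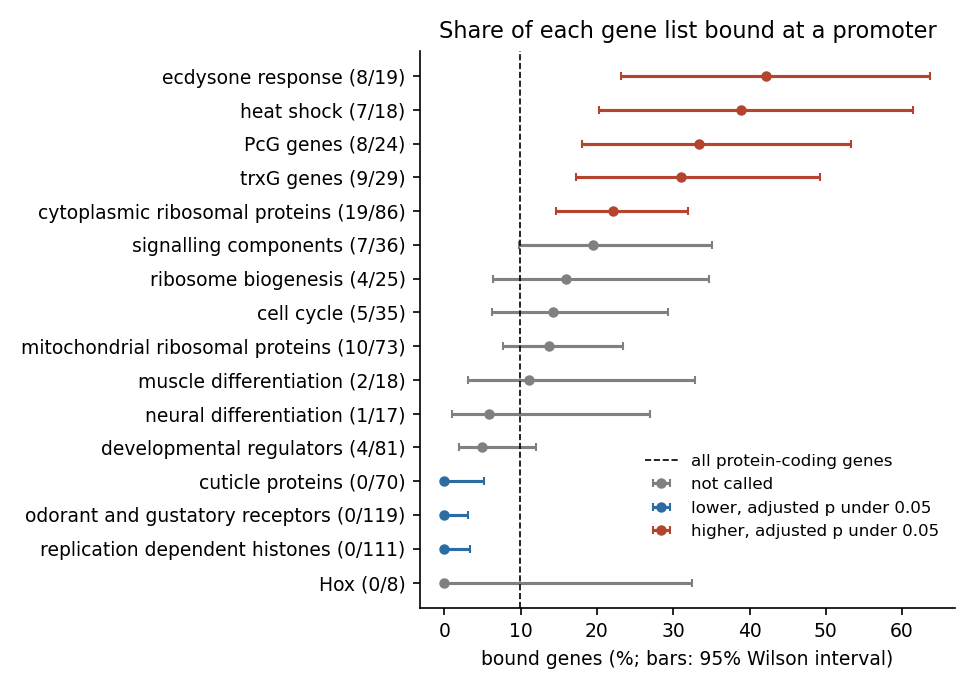
Share of bound genes in each of the 16 lists in percent, with 95% Wilson intervals; the dashed line marks 9.90%, the share of all protein-coding genes. Red lists were higher and blue lists lower at an adjusted p under 0.05, from 42.1% for ecdysone response to 0 for histones, receptors and cuticle proteins.

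None of the 8 Hox promoters was bound (adjusted exact p = 1), where a count of 0 allows a share of up to 37.5%. Antp had 4 optimal summits within its span and 5 kb on either side, and lab, pb, Dfd, Scr, Ubx, abd-A and Abd-B had 0. In the pooled list of peaks and background, 5 of the 8 promoters had a summit. Each Hox gene had pooled summits within the same distance, from 2 at Dfd to 45 at Antp. Sites further away were not counted. Among other developmental regulators known as Polycomb targets, 4 of 81 were bound (4.94%; adjusted exact p = 0.300), with the strongest summit at tin, a heart mesoderm homeobox gene (3R 21378755, signal 234). The counts were 4 of 25 ribosome biogenesis genes (adjusted exact p = 0.429), led by Ns2 (signal 277), and 5 of 35 cell cycle genes (adjusted exact p = 0.478), led by E2f1 (123). Of 36 signalling genes 7 were bound (adjusted exact p = 0.148), led by puc, a JNK phosphatase gene (221). They passed with a promoter window of 1000 bp (adjusted exact p = 0.0145) and with each summit given to its nearest TSS alone, chosen after seeing the data (0.0272). The remaining counts were 1 of 17 neural genes, elav (271; adjusted exact p = 1), and 2 of 18 muscle genes, led by how (96.2; adjusted exact p = 0.797).

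None of the 8 calls was stable under every alternative. Without replicate 1, the gap to other genes fell from 23.5 to 12.1 points for Polycomb group (adjusted exact p = 0.108), from 12.3 to 6.37 for cytoplasmic ribosomal protein (0.108) and from 29.0 to 13.5 for heat shock genes (0.119). Without replicate 2, the gap of the ribosomal protein genes was 22.1 points (adjusted exact p = 1.16e-06). In the stronger part of the peak set, the adjusted exact p was 0.210 for Polycomb group and ribosomal protein genes and 0.0616 for Trithorax group genes. It was 0.0588 for heat shock and 0.0879 for cuticle protein genes. The gaps of these lists there were 7.04, 3.85, 11.8, 16.8 and −5.50 points in this order, with 763 genes bound in place of 1381. Among genes with a pooled-list summit, ecdysone response (adjusted exact p = 0.244), ribosomal protein (0.564), receptor (0.264) and cuticle protein genes (0.0637) did not pass. The receptor and cuticle protein lists then had only 9 and 15 members, and their gaps grew to −25.4 points each. Within 250 bp Polycomb group genes did not pass (adjusted exact p = 0.0674). Against lists matched on the number of TSSs and on divergent promoters, Trithorax group (adjusted exact p = 0.173), ribosomal protein (0.116) and cuticle protein genes (0.133) did not pass. With more classes of TSS number in this matching, chosen after seeing the data, Polycomb group (adjusted exact p up to 0.0554) and ecdysone response genes (up to 0.0668) did not pass either. Against circular shifts, a permutation that left 325 genes bound on average, no list passed (adjusted p between 0.648 and 0.959 for these 8). The histone, cuticle protein and receptor lists had 0 bound genes, the lowest value possible. Shifts also gave 0 often (permutation p before adjustment 0.825, 0.492 and 0.142), so this permutation could not call these lists lower.

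In 5 of 6 classes, genes that make no protein were bound less often than the 9.90% of all protein-coding genes. Here a TSS was the start of an annotated transcript, which for miRNA genes can be that of the precursor. Such a start need not be where transcription begins, so a low share does not show that promoters of these classes lack binding. Protein-coding genes with 1 TSS were bound in 6.57% of cases, a share inside the interval of the tRNA genes (3.42 to 8.77), and no test was made against these alone. Summits were within 500 bp of a TSS for 16 of 290 tRNA genes (5.52%; adjusted exact p = 0.0146), 143 of 3001 genes for other non-coding RNAs (4.77%; adjusted exact p = 9.52e-21), 9 of 260 miRNA genes (3.46%; adjusted exact p = 2.85e-04), 3 of 268 pseudogenes (1.12%; adjusted exact p = 1.61e-08) and 2 of 269 snoRNA genes (0.743%; adjusted exact p = 1.78e-09). None of 32 snRNA genes was bound, which did not pass (adjusted exact p = 0.0694, Fisher's exact test with adjustment over 6 classes).

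Summits carried the GAGA element, the sequence TATAAA and the Dref element more often than the sequence beside them. The GAGAG element recognised by GAGA factor occurred within 100 bp of 30.4% of summits and in 22.8% of windows 1000 bp away (exact McNemar test, two-sided, Benjamini-Hochberg adjustment over 17 motifs, adjusted p = 1.58e-09). The longer GAGAGAG was at 8.28% against 4.27% (1.06e-08). TATAAA, the sequence of the TATA box, was at 35.3% against 21.6% (adjusted exact p = 1.78e-26). It was matched on both strands at any place in the window, so a match need not be a TATA box of a promoter. TATCGATA, the element of the promoter factor Dref, was at 2.42% against 0.681% (adjusted exact p = 8.05e-07), CGATA, bound by the insulator protein BEAF-32, at 26.1% against 23.2% (0.0366), and GTATWTTT, a core promoter motif, at 8.32% against 4.58% (5.96e-08). Motifs found less often than in the flanks were GCCAT, the core of the Polycomb recruiter Pho, at 25.2% against 32.5% (adjusted exact p = 1.67e-08), and RRGGYGG, the Sp1 type motif, at 7.83% against 14.0% (4.00e-12). Core promoter motifs that did not pass were TCAKTY, the initiator (adjusted exact p = 0.0503), GGTCACAC (0.485) and CAGCTG (0.615). The other 6 motifs did not pass either, among them CAGGTAG of Zelda (1.06% against 1.40%) and the ecdysone receptor palindrome (0 against 0.0378%).

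Several of these motifs passed at promoter summits only. TATCGATA occurred at 5.10% of promoter summits against 0.606% of flanks (adjusted exact p = 2.03e-10), and at 0.218% of distal summits against 0.436% (0.968). GAGAG was at 32.9% against 22.9% (adjusted exact p = 7.09e-07) and at 27.5% against 24.97% (0.472), and CGATA at 32.5% against 24.0% (3.13e-05) and at 19.96% against 20.1% (1). GTATWTTT (adjusted exact p = 7.09e-07) and TCAKTY (43.0% against 37.0%, 0.00681) passed at promoters and not at distal summits (0.120 and 0.373). TATAAA, GAGAGAG, GCCAT and RRGGYGG passed at both. The difference between the places was not tested.

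The motif calls depended on the control sequence. Summits had a mean GC content of 36.7% and their flanks 42.3%, and flanks matched on GC content were tried after seeing the data. With these, the gap was 10.5 points for GAGAG, 6.39 in place of 13.7 for TATAAA and −2.99 in place of −7.34 for GCCAT, all still past the threshold. GTATWTTT (adjusted exact p = 0.316) and RRGGYGG (0.236) no longer passed, while YGAGYG, the Zeste motif (5.67 points, 2.23e-06), CAGCTG (2.65 points, 7.82e-04) and the GT repeat GTGTGTG (2.16 points, 0.00617) did. Within 50 bp of the summit the adjusted exact p was 0.0851 for GAGAG, 0.0562 for GAGAGAG and 1 for CGATA. CGATA also did not pass in the stronger part of the peak set (adjusted exact p = 0.201). Against promoters with no summit, TATCGATA was at 5.10% of promoter summits and 3.74% (Fisher's exact test, adjusted p = 0.0491), and the gap was 10.7 points for GAGAG, 9.42 for TATAAA, 2.13 for GTATWTTT, −5.22 for GCCAT and −2.99 for RRGGYGG. CGATA did not pass there (adjusted exact p = 0.219), GTGTGTG did (0.0491), and GGTCACAC was lower at the summits (−1.13 points, 0.0491). TCAKTY passed without replicate 2 (adjusted exact p = 1.46e-04) and with flanks 2000 bp away (4.56e-04), but its sign turned with matched flanks (−2.50 points, 0.125) and against promoters with no summit (−1.59 points, 0.390). GTGTGTG passed without replicate 1 (adjusted exact p = 0.0175).

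The corto gene itself (3R 5077779 to 5087072) had 4 optimal summits within 5 kb of it, at 3R 5083164 in a 3′ UTR, 5087246 at the promoter, and 5087989 and 5089977 in intergenic sequence. Their signals were 81.9, 102, 96.2 and 82.1, at ranks 2600, 1605, 1837 and 2587 of the 2644 peaks. Whether reads of the transgene added to these peaks was not tested. The count was 0 in the stronger part of the optimal set, 3 without replicate 1 and 1 without replicate 2.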

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

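On the older dm3 build, 8 peaks of the optimal set lay outside the chromosome arms, at places that no comparison of location, genes or motifs used. They were flagged for exceeding a fixed limit of 3 peaks, which is not a test. The concatenated unplaced sequence Uextra held 7 of them, with signals up to 216, and the mitochondrial genome held 1 with a signal of 89.6. They are part of the 2604 peaks counted on dm3. The pooled dm3 list had 42 peaks outside the arms.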

How the results depend on the processing

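Of 82 alternatives to the main results, 69 kept the side of the threshold, or a count within 1.5 times. Within these, bound genes ranged from 1037 to 1675 in place of 1381, and the divergent promoter gap fell from 23.6 to 8.68 points with each summit given to its nearest TSS alone, chosen after seeing the data. The alternatives that took the top of the pooled list or the arms alone changed nothing by construction, since the optimal set was the top of that list and lay on the arms. With the stronger part of the optimal set, bound genes numbered 763, 3 lists were called, and corto had 0 summits. Fewer peaks entered there, and the gaps of the lists that lost their call were smaller too. Whether the lower number of peaks alone ended these calls was not tested. Without one replicate each, the lists called were 5 to 9 in place of 8, the corto summits 1 to 3 in place of 4, and the promoter against distal difference was 0.0380 to 0.0402, no longer past the threshold. With genes that have a pooled-list summit as background, 3 lists were called and the histones had no member left. With circular shifts, 0 were called, where shifted summits bound fewer genes. Motif calls fell from 8 to 5 in windows of 50 bp, and the reason was not tested. The rank correlation of 0.44 became 0.49 in the stronger part, 0.52 as Pearson's r of log2 signals and 0.55 over the 12777 pooled peaks matched in both replicates, the last chosen after seeing the data. GGTCACAC turned lower (−1.13 points) against promoters with no summit, and CAGCTG higher (2.65 points) with flanks matched on GC content, also chosen after seeing the data; the cause was not tested. Among single lists, heat shock, Polycomb group and cytoplasmic ribosomal protein genes each lost their call in 4 of 13 alternatives, not counting the matched lists described elsewhere, cuticle proteins in 3, and ecdysone response, Trithorax group and receptor genes in 2; histones lost theirs in 3 of 12. TATAAA, TATCGATA and GCCAT kept theirs in 8 of 8, but with flanks matched on GC content TATAAA went from 13.7 to 6.39 points and GCCAT from −7.34 to −2.99. Unknown depth limits any statement on sites without a peak.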

Other observations

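Among the tests below, those chosen only after the result was seen were of coding summits outside promoters and of the 8-mer on the other arms. Further alternatives added after seeing the data are named with the processing above. The matched lists were changed from random draws to an exact calculation after their first values were seen, with more classes of TSS number added later. The numbers of summits per gene below were also looked up after their values were seen. With 1 group and no expression data, no biological explanation was tested for any pattern here.

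Some genes held many summits along their span and 5 kb on either side. They were taken as those with the most of all 13945 genes, so their counts are given as values and were not tested against chance. sbb, which encodes a nuclear corepressor (2R 18278198 to 18357296), held 16, Eip75B 14, Tet and tara 13 each, and Tlk, bun and ush 11 each. ph-p (X 2126210 to 2138371), only 12.2 kb long, held 10, as did lola, kirre, which spans 394 kb, and each of the short neighbours CG12078 and CG43389 at 3L 3243274 to 3249044. The windows of CG12078 and CG43389 overlap, so the same summits can count for both. The region around corto had 0.674 pooled summits per kb, more than around 94.4% of genes, whose median was 0.196.

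Coding sequence was nearly free of summits: 3 of the 1488 outside promoters. A pull towards promoters is argued against, as the coding share outside promoters was 0.202% and the lowest of the shifts 12.2%. AT-rich sequence at the summits may account for part, but not for the whole: positions matched on GC content lay in coding sequence in 5.33% of cases on average, and 4.58% in the lowest of 100 draws, against 0.113% of summits. These shares include promoters, where summits were frequent. Outside promoters, the matched positions had 5.97% on average and the summits 0.202%, with the matching done on all summits. The strongest peaks of each replicate alone had 3 and 4 coding summits. The control reads and the peak calling stay open.

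Genes with many TSSs were bound more often, from 6.57% of those with 1 TSS to 40.2% of those with 4 or more, and this may raise the share of a list. Against random lists matched on divergent promoters and on the number of TSSs, with 4 or more as 1 class, the adjusted exact p was 0.00342 for heat shock genes (38.9% against a matched mean of 8.37%), which argues against these as the whole cause, though neighbouring genes were counted singly. For Polycomb group (33.3% against 13.0%) and ecdysone response genes (42.1% against 17.9%) it was 0.0493 each, but up to 0.0554 and 0.0668 with more classes of TSS number, so that these lists cannot be told apart from this explanation. For Trithorax group genes the matched mean rose to 17.3%, from 9.86% of other genes, and their 9 bound members lay within the middle 95% of matched lists, 2 to 9, so that the call ended (0.173). Cytoplasmic ribosomal protein genes, at 22.1% against 14.0%, cannot be told apart from it either, with 19 bound where matched lists had 6 to 18 but an adjusted exact p of 0.116.

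A search of the 26969 8-mers with at least 3 G or C bases at the summits on X, 2L and 3L put CACTGTGC first, with 81 of 1529 summits against 12 flanks, followed by CACAGTGG with 78 against 13. Sequences of this family had first been noticed in a look at all arms, so 2R, 3R and 4, left out of this search, were not wholly unseen. On them CACTGTGC was also more frequent, which argues against a chance pick only in part: 31 of 1115 summits against 13 flanks, a difference of 1.61 points (adjusted exact p = 0.0119). Base composition is argued against as well, with 6 of the flanks matched on GC content and a difference of 2.24 points (adjusted exact p = 1.27e-04). Over all arms, those of the search included, CACTGTGC lay at 6.2% of the 500 strongest summits and 2.4% of the 500 weakest. It lay at 3.63% of promoter and 4.58% of distal summits (Fisher's exact test, p = 0.313). An unidentified factor that binds this sequence may be present at part of the sites, a hypothesis that was not tested.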
